A study of Lactiplantibacillus plantarum with 6 samples.

How the data were processed

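RNA was measured in 6 cultures of L. plantarum CAUH2, 3 untreated and 3 exposed to 5 mM H2O2 for 30 min. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 3 µg of total RNA with an Illumina TruSeq RNA kit, which does not mark strand. Whether ribosomal RNA was depleted is not given in the sources used here. Per the submitters' processing notes, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0 were used, with no role or order stated. The genome build is not given in the sources used here. Coordinates are those of the authors' table, counted from 1, and all genes named lie on the map of that table.

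The authors deposited a table of 3093 rows, of which 3052 carry a locus tag, 27 are named as predicted small RNAs and 14 as further transcripts such as Novel00002. Per the file headers it gives a read count per gene and library, and these deposited counts, whole numbers without normalization, were the values tested. The same table and a separate file per library hold FPKM values made by the authors from the counts, gene length and the column total, and the own FPKM file of H2O2 replicate 1 repeats the FPKM values of replicate 2, while the table has distinct columns for each. FPKM values entered no test. The authors' table also gives, per the file headers, a mean normalized signal per group (mean count after division by size factors), a log2 fold change, a p-value with its adjusted value and a call per gene, which were only set beside the results obtained here. There, 74 log2 cells are not numbers.

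A single gene, A1F92_00050, holds a cell that is not a number in the count column of H2O2 replicate 1 and was left out of all tests. All rows name a gene or transcript. Of the 3093 rows, 85 had 0 counts in all 6 libraries, among them 15 of 16 ribosomal RNA genes and 45 of 72 transfer RNA genes, so these RNAs are not described. Total counts ranged from 4625904 to 5197912. Groups were taken from the treatment label, and the labels give no batch. Libraries of the same group were compared by a chi-square test of their counts over genes. The statistic per degree of freedom was between 3.45 and 7.21 for control pairs and between 16.8 and 47.7 for H2O2 pairs. That test covers counting error only and was used to look for a library present more than once, and no pair was that close. The common biological coefficient of variation was 0.084, with 0.056 in the control libraries alone and 0.128 in the H2O2 libraries alone.

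Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr with its default minimum count of 10 and minimum total of 15, TMM scaling, glmQLFit and glmQLFTest on group, two-sided, with Benjamini-Hochberg adjustment over the 2660 genes kept and a threshold of 0.05. Verbs such as rose and fell are used for genes past that threshold. TMM factors were 2.02, 2.12 and 2.10 in the control libraries and 0.500, 0.443 and 0.503 in the H2O2 libraries. Standard errors of log2 folds were taken as the size of the fold divided by the square root of its F statistic. CPM values are counts scaled to a common library size with the TMM factors, as mean ± SD over 3 libraries. An exact permutation test of 3 against 3 libraries cannot go below a p of 0.1, so single genes rest on the model fitted across genes. Folds of genes with 0 counts in a group were set against a floor of 3 counts over the group on the TMM scale. The lower limit of a 95% counting interval stands beside them, and folds of genes with 1 to 3 counts carry the whole interval. Both cover counting error only.

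A set of 24 gene lists was fixed before the data were examined and matched to whole gene symbols or product text. Genes matched by mistake were kept, and the lists were tested again without them. The member counts given for a list include such genes. Lists were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, beside camera with an estimated correlation and fry. Gene Ontology terms of the authors' annotation with 10 to 300 tested genes were tested in the same way. The genes named were chosen by a rule written before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes past the threshold, with groups that did not overlap, at least 10 CPM on average and a product that is not hypothetical, a transposase, a ribosomal RNA or a transfer RNA. It also took the 2 largest changes and 1 of the opposite direction in each list, and a fixed set of stress genes whatever their value. It gave 106 genes, of which those that best describe each list are printed. Of these genes, 17 overlap another gene of the table, by at most 20 bases and with 0 on the opposite strand, and 11 share their symbol with another gene, so that reads of similar copies are uncertain. None of the gene identifiers matched the reference gene table at hand, of another strain, so symbols and products are those of the authors' table.

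The code was tested on simulated counts drawn from the mean composition of the control libraries and the sizes of all libraries. Most genes were left unchanged by design, which is what TMM assumes, so the simulation cannot say which scaling suits the real libraries. Over 2681 genes of even composition, TMM recovered 80% of genes changed 1.5-fold, 95.9% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and called 0.28% of unchanged genes. Over 2622 genes with the 3 abundant RNAs rnpB, ssrA and Novel00002 raised 8-fold, TMM recovered 71.4%, 89.4%, 98% and 100% at the same folds and called 0.33% of unchanged genes, whereas library totals called 98.56% of them. Camera gave a list of 20 raised genes an adjusted p of 5.35e-14 and called 0 of 24 unchanged lists. Simulated genes were drawn independently of each other, so this check does not cover correlation between genes of a list.

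The alternatives were DESeq2 1.42.0, relative-log-expression and upper-quartile scaling, library totals without TMM, no filter on low counts, at least 10 CPM in at least 3 libraries, the replicate number as a block, removal of ribosomal and transfer RNA and the 10 most abundant genes, limma-voom, glmTreat against a fold of 2, and leaving out each library. Further alternatives were chosen after seeing the data: library totals without the 3 abundant RNAs, lists without mistaken matches, and several of the fits above applied to lists and terms. Figures and correlations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.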

Results

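The series profiled the transcriptome of Lactiplantibacillus plantarum strain CAUH2, a lactic acid bacterium, by RNA sequencing of total RNA. All cultures were grown in MRS, a rich medium for lactobacilli, at 37 °C to an OD600 of about 0.8. In 3 cultures the cells were then held in MRS with 5 mM hydrogen peroxide (H2O2) for 30 min, and 3 untreated cultures formed the control group, with the 3 libraries of each group described as biological replicates. Gene counts summed to 4625904, 4735560 and 4766713 in the control libraries and to 5197912, 5096725 and 5158205 in the H2O2 libraries. The single comparison of the design asked which transcripts differed between cells exposed to H2O2 and untreated cells.

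H2O2 was followed by a rearrangement of most of the transcriptome. After TMM scaling, 19 of 23 genes of peroxide and thiol defence rose, 12 of them also on library totals. The thioredoxin gene trxH, the glutathione reductase gene gshR4 (A1F92_15260), the small heat-shock gene hsp1 and the pyruvate dehydrogenase gene pdhD rose by more than 32-fold. Of the lists fixed beforehand that camera called, 2 fell in most genes, 48 of 55 for the cell wall and 18 of 23 for aminoacyl-tRNA synthetases. Lists that camera did not call also fell in most genes, such as capsule and exopolysaccharide with 18 of 23. At the same time 3 short transcripts, the RNA of ribonuclease P (rnpB), ssrA and Novel00002, came to make up 51.5% ± 1.55 of all counts in the H2O2 libraries against 12.6% ± 0.56 in the control libraries (SD, n = 3). Among 2660 genes tested, 1055 were higher and 1174 lower with H2O2 in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 after TMM scaling, and 753 and 860 of them changed by at least 2-fold. In 2257 genes (84.8%) the 3 H2O2 libraries lay wholly above or wholly below the 3 control libraries, a pattern that chance alone gives in 10% of genes.

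The balance of rises and falls rested on the scaling. TMM sets the median gene close to no change (log2 fold −0.16), and scaling to library totals alone placed it at −2.26, a shift of 2.11 between the scales. On library totals 287 genes were higher and 2195 lower, 11.6% of the changed genes being higher in place of 47.3%, and 591 genes higher after TMM were lower. All log2 folds and CPM values (read counts scaled to a common library size) below are on the TMM scale and are relative to that shift, and the library-total value stands beside each direction that it turned.

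**Figure D1:**
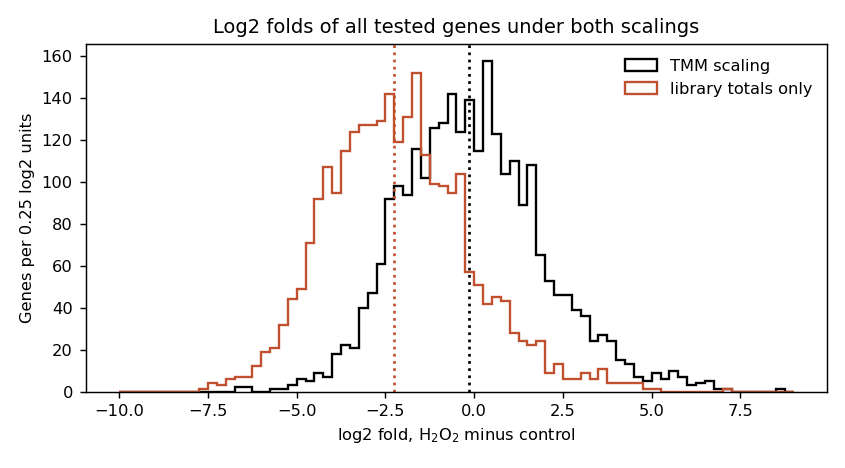
Histogram of the log2 fold change (H2O2 minus control, x axis) of the 2660 tested genes in bins of 0.25 (number of genes on the y axis) under TMM scaling and under library totals, with a dotted line at each median. The median lies at −0.16 with TMM and at −2.26 with library totals, so the direction of 591 genes depends on the scale.

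A few short transcripts took up much of the sequence. The gene rnpB, the catalytic RNA that trims transfer RNA precursors (A1F92_07365, positions 1569830 to 1570204), went from 8.35% ± 0.317 to 28.4% ± 1.02 of all counts (SD, n = 3), and ssrA, the transfer-messenger RNA that frees stalled ribosomes, from 3.42% ± 0.152 to 10.7% ± 0.889. A transcript named Novel00002 in the authors' table (positions 913542 to 913802), for which that table gives no function, went from 0.858% ± 0.122 to 12.4% ± 2.76. The 6S RNA ssrS, which binds RNA polymerase, went from 0.231% ± 0.0142 to 2.26% ± 0.83. On the TMM scale their log2 folds were 3.88 (SE 0.103), 3.75 (SE 0.113), 5.97 (SE 0.19) and 5.42 (SE 0.269), all past the edgeR threshold. The RNA of the signal recognition particle, ffs, moved the other way (log2 fold −0.75, SE 0.273, adjusted p = 0.0206 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). RnpB, ssrA, Novel00002 and ssrS were chosen after their counts were seen, and ffs was named in a test written before its value was seen. The median count per gene fell from 198 ± 4.93 in the control libraries to 43.7 ± 4.93 in the H2O2 libraries, and the number of genes without a count went from 140 ± 3.06 to 262 ± 24.8.

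**Figure D2:**
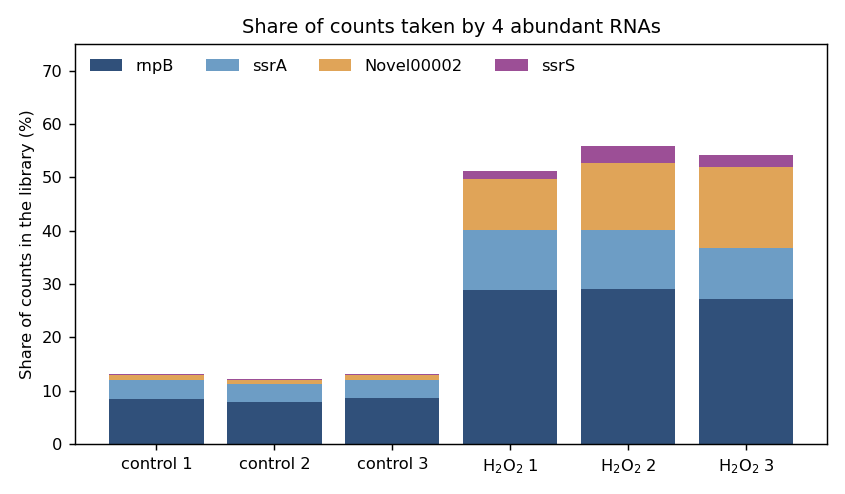
Stacked bars of the percent of all counts (y axis) taken by rnpB, ssrA, Novel00002 and ssrS in each of the 3 control and 3 H2O2 libraries (x axis). RnpB lies between 7.99% and 8.59% in the control libraries and between 27.2% and 29.0% in the H2O2 libraries.

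Genes of peroxide and thiol defence rose together. Of 23 members tested, 19 rose and 3 fell, with a median log2 fold of 2.59 (12 higher and 10 lower on library totals), and the counts were equal when adjusted over the list alone. The camera test of the list against all other genes gave an adjusted p = 1.25e-07 after Benjamini-Hochberg adjustment over the 24 lists. The adjusted p = 0.263 with an estimated correlation was the highest over 17 alternatives, the lowest being 9.57e-09. Several genes for thioredoxins, small proteins that reduce disulfides, were among the most strongly raised, but the thioredoxin gene A1F92_00955, looked up outside the naming rule, fell to −0.50 (SE 0.132). TrxH (A1F92_10960) went from 27.7 ± 2.46 to 1928 ± 134 CPM (SD, n = 3; log2 fold 6.12, SE 0.107), and trxA3, trxA2 (A1F92_15215) and trxA2 (A1F92_09565) reached log2 folds of 5.59 (SE 0.141), 5.40 (SE 0.243) and 3.81 (SE 0.0927). The glutathione reductase gene gshR4 (A1F92_15260, positions 3271769 to 3273100), whose enzyme regenerates reduced glutathione, went from 21.3 ± 1.65 to 1935 ± 299 CPM (log2 fold 6.5, SE 0.137). The NADH peroxidase gene npr2, whose product breaks down H2O2, rose by a log2 fold of 2.59 (SE 0.0843), while the other annotated NADH peroxidase, A1F92_06180, gave −0.73 (SE 0.386) and missed the threshold (adjusted p = 0.096 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The latter passed it on library totals (−2.81), and without H2O2 replicate 3 at −1.35 (adjusted p = 0.0176 in the same edgeR test with Benjamini-Hochberg adjustment; range over 15 alternatives, DESeq2 and limma-voom included, 1.78e-06 to 0.32). Thioredoxin reductase trxB, the 2-Cys peroxiredoxin tpx and the catalase kat rose by 0.74 (SE 0.0837), 0.75 (SE 0.0894) and 1.17 (SE 0.0915) after TMM and were lower on library totals, at −1.37, −1.36 and −0.94. Of the remaining members that fell, the NrdH redoxin gene nrdH, whose product donates electrons to ribonucleotide reductase, reached −0.61 (SE 0.121).

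Regulators went in both directions. The gene fur (A1F92_13475, positions 2867617 to 2868099), annotated as a repressor of the family that senses metals or peroxide, went from 56.2 ± 3.79 to 2170 ± 335 CPM (SD, n = 3; log2 fold 5.27, SE 0.126). Spx proteins steer RNA polymerase towards thiol-stress genes: spx1 rose by 5.00 (SE 0.109) and spx5 by 2.28 (SE 0.092; 0.17 on library totals, not past the threshold), spx3 fell to −1.02 (SE 0.0807), and spx2 was higher after TMM (1.22, SE 0.168) and lower on library totals (−0.88). Only spx3, which fell, is given as Spx by its product. The others are Spx genes by symbol only. The product of spx1 is given as hypothetical, and those of spx2 and spx5 as ArsR family regulators. Dps proteins store iron and shield DNA. The copy dps1 (A1F92_15225) rose by 5.81 (SE 0.181). The copy A1F92_13000 had 0 counts over the control libraries and 59 over the H2O2 libraries. It was 77.6-fold higher against a floor of 3 counts over the group (lower limit of the 95% counting interval 61.1). Both carry the symbol dps1, as A1F92_09565 and A1F92_15215 share trxA2, so reads from similar copies may have been split between them.

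Oxygen-consuming oxidases went in both directions. Of 10 tested, 7 rose and 3 fell (3 higher and 6 lower on library totals; the TMM counts were equal when adjusted over the list alone), with a camera adjusted p = 0.0251. The adjusted p = 0.429 with an estimated correlation was the highest of 17 alternatives, down to 0.0166, and the call was also lost on library totals (adjusted p = 0.0959, or 0.0583 without the 3 RNAs) and with limma-voom (adjusted p = 0.0719). The pyruvate oxidase genes pox2 and pox1, whose enzymes form acetyl phosphate and H2O2 from pyruvate, rose by 4.61 (SE 0.0956) and 3.56 (SE 0.133). Of the NADH oxidases, nox2 fell to −1.40 (SE 0.156), and nox5 was higher after TMM (1.47, SE 0.101) and lower on library totals (−0.64). Of 20 genes matched to iron, manganese and iron-sulfur handling, 3 of them by mistake, 9 rose and 8 fell (4 and 14 on library totals). Camera did not call the list (adjusted p = 0.141), except with a filter of 10 CPM (adjusted p = 0.0422, range over 17 alternatives 0.0422 to 0.581). Besides fur, list members that rose included iron-sulfur assembly genes, looked up outside the naming rule. The genes sufB, sufU and sufS rose by 3.12 (SE 0.106), 2.94 (SE 0.153) and 2.47 (SE 0.101). SufD and sufC rose by 2.07 (SE 0.101) and 1.07 (SE 0.118), less than the shift of 2.11 between the scales. A1F92_06555, annotated for iron-sulfur cluster biosynthesis, fell to −2.33 (SE 0.18). The manganese transporters mntH1 and mntH3 fell to −1.30 (SE 0.0985) and −2.35 (SE 0.353). The gene fhuB, a permease for iron-loaded siderophores, went from 49 counts over the control libraries to 0. It was 4.14-fold lower against the same floor (lower limit of the 95% counting interval 3.24).

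**Figure D3:**
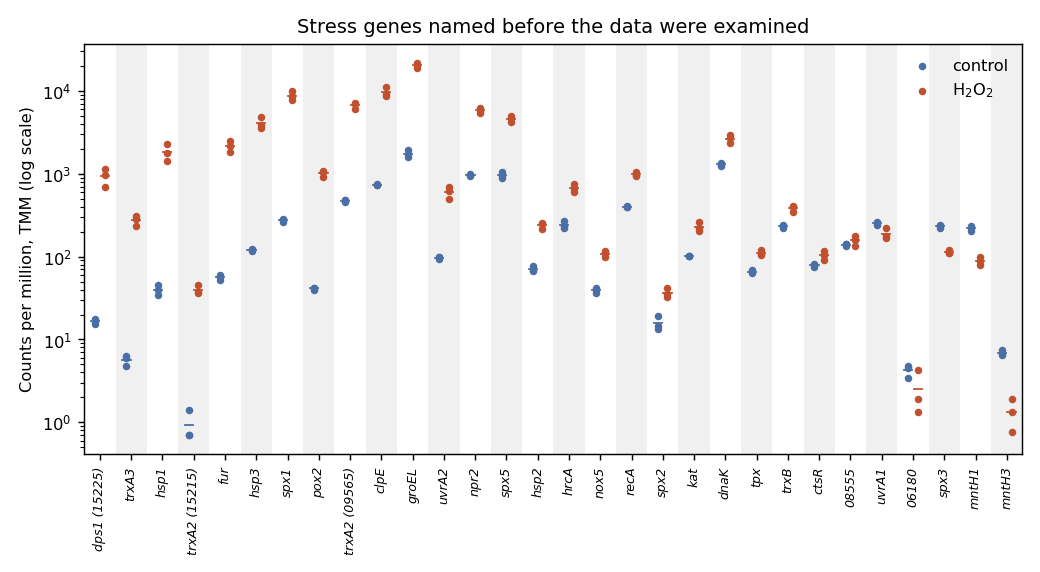
CPM after TMM scaling (y axis, log scale) of stress genes chosen before the data were examined, with a point for each of the 3 control and 3 H2O2 libraries and a line at each group mean; the dps1 copy with no control counts is left out. Genes run from the largest rise (dps1, log2 fold 5.81) to the largest fall (mntH3, −2.35), and trxB, tpx, kat, nox5, spx2, recA, A1F92_08555, ctsR, dnaK, hrcA and hsp2 lay lower, not higher, on library totals.

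Chaperones and proteases rose after TMM in 19 of 21 members and fell in 2 (6 and 15 on library totals), with a median log2 fold of 1.36, and the TMM counts were equal when adjusted over the list alone. The camera adjusted p = 7.15e-05 stood beside an adjusted p = 0.429 with an estimated correlation, the highest of 17 alternatives, the lowest being 7.22e-06. The small heat-shock protein genes hsp1 and hsp3, whose products hold unfolded proteins, rose by 5.53 (SE 0.174) and 5.10 (SE 0.119). GroEL, the folding chamber, went from 1751 ± 161 to 20607 ± 1463 CPM (SD, n = 3; log2 fold 3.56, SE 0.0986), and clpE, an unfoldase of the Clp protease, rose by 3.70 (SE 0.105). Smaller TMM rises of dnaK (1.03, SE 0.0867), hsp2 (1.76, SE 0.0909), and the repressors hrcA (1.49, SE 0.103) and ctsR (0.40, SE 0.0971) were falls on library totals, at −1.08, −0.34, −0.62 and −1.71. The membrane protease ftsH was lower after either scaling (−0.41, SE 0.0707).

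DNA repair genes split. Of 43 tested, 20 rose and 17 fell (3 and 37 on library totals), the list median was 0.18 and camera made no call (adjusted p = 0.708). Endonuclease III, nth1, which removes oxidised bases, rose by 4.04 (SE 0.0982), and uvrA2, a copy of the damage-recognition subunit of nucleotide excision repair, by 2.64 (SE 0.112), while uvrA1 fell to −0.41 (SE 0.101) and the helicase gene recQ2 to −2.79 (SE 0.294; −3.72 without H2O2 replicate 3). The recombinase gene recA was higher after TMM (1.29, SE 0.0755) and lower on library totals (−0.81). The repressor of the SOS response, LexA (A1F92_08555), gave 0.18 (SE 0.0988; adjusted p = 0.108 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and −1.93 on library totals. It passed the threshold upward at 0.28 without H2O2 replicate 2, at 0.25 with relative-log-expression scaling and at 0.30 with a filter of 10 CPM (adjusted p = 0.0115, 0.0237 and 0.0122 in the same edgeR test with Benjamini-Hochberg adjustment). The range over 16 alternatives, which include DESeq2 and limma-voom beside the edgeR test with Benjamini-Hochberg adjustment, was 4.79e-10, for the fall on library totals, to 0.448.

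Among the 10 largest rises taken by the naming rule were genes of sugar and glycerol uptake and use. The maltodextrin transporter permeases mdxF (A1F92_00710, positions 151755 to 153044) and mdxG rose by 7.15 (SE 0.197) and 6.68 (SE 0.221), and galM2, a sugar mutarotase, by 6.90 (SE 0.112). The glycerol channel glpF3 rose by 6.75 (SE 0.116) and the 6-phospho-beta-glucosidase pbg4 by 6.31 (SE 0.122). Of 50 genes of the phosphotransferase system (PTS), which imports and phosphorylates sugars, 36 rose and 9 fell (18 and 25 on library totals; the TMM counts were equal when adjusted over the list alone), led by pts9C (A1F92_09850; 6.63, SE 0.311) and pts19D (A1F92_09845; 6.17, SE 0.324). Among those that fell, A1F92_04020, a IIA subunit with few counts, gave −2.15 (SE 0.626), −1.55 without H2O2 replicate 1 and −3.78 without H2O2 replicate 3. Camera gave the PTS list an adjusted p = 7.15e-05 and an adjusted p = 0.263 with an estimated correlation, the highest of 17 alternatives, down to 3.66e-06. Both pts9C and pts19D share their symbols with other genes. Both had few control counts, with means of 0.34 and 0.28 CPM in the control libraries and of 35.6 and 21.0 CPM with H2O2. The pyruvate dehydrogenase genes pdhD (A1F92_08920) and pdhC, for subunits of the complex that makes acetyl-CoA, rose by 6.68 (SE 0.113) and 6.40 (SE 0.113), pdhD from 26.7 ± 2.23 to 2737 ± 226 CPM (SD, n = 3), while the acetate kinase gene ack1 fell to −2.47 (SE 0.115).

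The lists of central carbon metabolism were less even than these genes. Of 27 genes of pyruvate and acetate metabolism 12 rose and 10 fell (8 and 19 on library totals), with a median of 0.04 and a mean of 0.97 and a camera adjusted p = 0.031 (adjusted p = 0.271 with an estimated correlation; range over 17 alternatives 0.012 to 0.311, the highest with limma-voom, the call also lost on library totals). Of 22 glycolytic genes 15 rose and 6 fell (5 and 16 on library totals), with a camera adjusted p = 0.0251 (adjusted p = 0.429 with an estimated correlation; range over 17 alternatives 0.014 to 0.498, the highest on library totals, the call also lost on library totals without the 3 RNAs and without the 10 most abundant genes). In both lists the TMM counts were equal when adjusted over the list alone. The lactate dehydrogenase gene ldhL1, for the enzyme that turns pyruvate into lactate, went from 671 ± 63.0 to 8569 ± 549.8 CPM (SD, n = 3, log2 fold 3.67, SE 0.0972). The gene pgm8, annotated as a phosphoglycerate mutase, fell to −2.84 (SE 0.159). The glycolytic genes that fell averaged at most 97.3 CPM in the control libraries. Looked up outside the naming rule, the abundant genes gapB and pyk rose by 2.57 (SE 0.0841) and 2.55 (SE 0.0851). A more abundant phosphoglycerate mutase gene, gpmA (4336 CPM in the control libraries), rose by 1.78 (SE 0.0796), less than the shift of 2.11 between the scales.

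Cell wall genes fell almost throughout. Of 55 genes of peptidoglycan and teichoic acid synthesis 48 fell and 6 rose, with a median log2 fold of −1.53 (53 lower on library totals; the TMM counts were equal when adjusted over the list alone). The camera adjusted p = 1.25e-07 became an adjusted p = 0.182 with an estimated correlation, the highest of 17 alternatives, the lowest being 9.67e-09. MurA2, for the first committed step of peptidoglycan synthesis, went from 205 ± 4.63 to 15.3 ± 3.72 CPM (SD, n = 3, log2 fold −3.74, SE 0.128). The gene pbpX2 (A1F92_05020) fell to −3.50 (SE 0.148). It is a penicillin-binding protein gene by its symbol only, which another gene shares, and its product is given as hypothetical. In contrast pbpX1, annotated as a D-Ala-D-Ala carboxypeptidase, rose by 2.64 (SE 0.273, and 0.55 on library totals, not past the threshold). The deepest of the 10 largest falls taken by the naming rule, which needs at least 10 CPM on average there, was that of A1F92_14085 (positions 3000889 to 3001956), annotated as a muropeptidase that cuts the cell wall, from 3673 ± 154 to 97.2 ± 22.5 CPM (log2 fold −5.24, SE 0.139). Of 23 capsule and exopolysaccharide genes 18 fell and 1 rose, and the list missed the camera threshold (adjusted p = 0.0678). Camera called it with limma-voom, without control replicate 2, without control replicate 3 and with a filter of 10 CPM (adjusted p = 0.00841, 0.0439, 0.0478 and 0.049; range over 17 alternatives 0.00841 to 0.727). In that list cps2E, a priming glycosyltransferase gene, went from 57 counts over the control libraries to 0. It was 4.82-fold lower against a floor of 3 counts over the group (lower limit of the 95% counting interval 3.79). The gene that rose, A1F92_05130 (1.0, SE 0.435), was lower on library totals (−1.09), and its upward call was absent under 10 of 15 alternatives, among them DESeq2, no filter on low counts and leaving out each of 4 libraries. Without control replicate 2 it stood at 0.66 (adjusted p = 0.133 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; range over 15 alternatives, DESeq2 and limma-voom included, 0.0184 to 0.569).

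Genes that serve translation and nutrient supply followed different courses. Of 23 aminoacyl-tRNA synthetases, which charge transfer RNAs, 18 fell and 4 rose (23 lower on library totals; the TMM counts were equal when adjusted over the list alone), with a camera adjusted p = 0.015. The adjusted p = 0.581 with an estimated correlation was the highest of 17 alternatives, down to 1.73e-05. PheS and metS fell to −2.81 (SE 0.117) and −2.61 (SE 0.0965), and ileS was higher after TMM (1.54, SE 0.0789) and lower on library totals (−0.58). Other deep falls were those of A1F92_00215, annotated as a protein that binds elongation factor G (−4.86, SE 0.211), the amino acid permease A1F92_00485 (−4.14, SE 0.158), the di- and tripeptide transporter dtpT (−3.52, SE 0.131) and the multidrug transporter A1F92_10515 (−4.68, SE 0.225). Of 52 genes matched as ribosomal proteins 31 rose and 16 fell (2 and 47 on library totals, camera adjusted p = 0.176), from rplQ at 2.97 (SE 0.0899) to rpsB at −3.43 (SE 0.115). Among those that fell was 1 gene matched by mistake, the methyltransferase gene A1F92_08325.

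**Figure D4:**
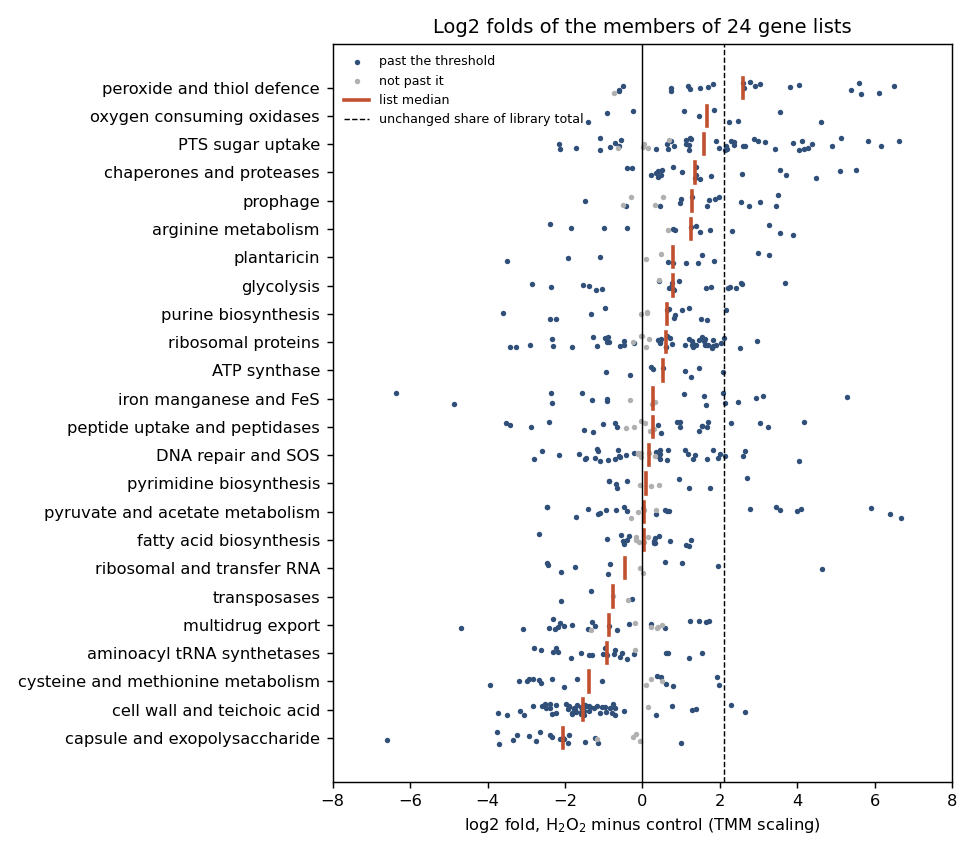
Log2 fold change (H2O2 minus control, TMM scale, x axis) of each tested member of the 24 gene lists fixed before the data were examined (y axis), coloured by whether the gene passed the edgeR threshold, with a bar at each list median, a dashed line at 2.11 where a gene keeps its share of the library total, and cps2E and fhuB, at 0 counts with H2O2, drawn at fitted values that are no bounds. Medians run from −2.05 (capsule) to 2.59 (peroxide and thiol defence), and on library totals every median except that of peroxide and thiol defence (0.47) lay below 0.

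The remaining lists were not called by camera. Of 20 genes of cysteine and methionine metabolism 6 rose and 11 fell (18 lower on library totals; adjusted p = 0.141), with the methionine synthase gene A1F92_11280 and the cystathionine beta-lyase gene cblA1 at −3.93 (SE 0.306) and −3.19 (SE 0.267), the latter −3.86 without H2O2 replicate 3. Of 15 arginine genes 10 rose and 4 fell (3 and 9 on library totals; adjusted p = 0.349), argH, for the last step of arginine synthesis, by 3.56 (SE 0.0979). Of 27 multidrug exporters 6 rose and 15 fell (25 lower on library totals; adjusted p = 0.176), and of 30 genes of peptide use 14 rose and 9 fell (3 and 26 on library totals; adjusted p = 0.259), the peptidase gene pepO by 4.17 (SE 0.0898). Of 9 genes matched as ATP synthase 7 rose and 2 fell (8 lower on library totals; adjusted p = 0.32). Among them atpC and atpD, subunits of the catalytic part, rose by 2.09 (SE 0.0948; −0.021 on library totals, not past the threshold) and 1.46 (SE 0.0777). On library totals atpD was lower (−0.65).

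Nucleotide and lipid synthesis were mixed after TMM and mostly lower on library totals. That held for 15 of 17 genes of the purine list, 10 of 12 of the pyrimidine list and 21 of 21 of the fatty acid list. Of the 17 purine genes, 1 of them matched by mistake, 9 rose and 5 fell. The list had a median of 0.63, a mean of 0.01 and a downward camera direction (adjusted p = 0.706). PurA, for a step towards AMP, fell to −3.61 (SE 0.141). Of 12 genes matched as pyrimidine synthesis, 2 of them by mistake, 4 rose and 5 fell (median 0.08, mean 0.31, camera downward, adjusted p = 0.894). PyrB, for the first committed step, rose by 2.69 (SE 0.321, and 0.59 on library totals, not past the threshold). Of 21 fatty acid genes 9 rose and 7 fell (median 0.03, mean −0.01, camera downward, adjusted p = 0.897). AcpS, which activates the acyl carrier protein, fell to −2.68 (SE 0.164), and the enoyl reductase gene fabI was higher after TMM (1.26, SE 0.0933) and lower on library totals (−0.85).

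Mobile and antimicrobial genes changed in part. Of 19 genes matched as prophage 13 rose and 2 fell (3 and 9 on library totals), 2 of the highest being the tail protein A1F92_10170 (3.50, SE 0.343) and the capsid protein A1F92_10200 (3.44, SE 0.323; 2.82 without H2O2 replicate 3). Camera did not call that list (adjusted p = 0.527), except on library totals (adjusted p = 0.0417; range over 17 alternatives 0.0417 to 0.875). Of 13 plantaricin and bacteriocin genes 8 rose and 3 fell (2 and 8 on library totals; adjusted p = 0.448), and plnI, an immunity gene with 51 counts over the control libraries and 1 over the H2O2 libraries, in replicate 3, was 12.9-fold lower (95% counting interval 2.22 to 521). Of 5 transposases 3 fell, or 2 adjusted over the list alone (5 lower on library totals; adjusted p = 0.571). Of 12 rows matched as ribosomal or transfer RNA 4 rose and 6 fell (1 and 10 on library totals; adjusted p = 0.527), but 8 of them are enzymes that act on these RNAs or bind them, such as the methyltransferase A1F92_05680 (−2.46, SE 0.166). In 23 of the 24 lists the counts adjusted over the list alone equalled those over all genes.

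Across the Gene Ontology terms of the authors' annotation, camera called 33 of 585 terms higher and 16 lower. With an estimated correlation 0 terms were called by camera, 54 having an unadjusted p under 0.05. The term cell redox homeostasis had 16 of 26 genes higher and 6 lower (camera adjusted p = 0.00024; adjusted p = 0.5 with an estimated correlation; range over 16 alternatives 2.09e-05 to 0.5). Amino acid transmembrane transporter activity had 15 of 16 lower (camera adjusted p = 0.0038; adjusted p = 0.5 with an estimated correlation; range over 16 alternatives 0.00278 to 0.5). RNA modification had 25 of 29 lower and 3 higher (camera adjusted p = 0.0125; adjusted p = 0.5 with an estimated correlation; range over 16 alternatives 0.00178 to 0.5). The authors' deposited table marks 970 genes up and 1020 down. Of its calls, 928 were among those higher in the edgeR test and 1017 among those lower, 0 had the opposite direction, and 284 genes changed in the edgeR test carry no call there. Across 2655 genes the log2 folds of the deposited table and of the edgeR fit had a Pearson r of 0.9999, as a description across genes that are not independent replicates.

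Of the 8 lists called by camera, 0 were called with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry called 22 of the 24 lists. Fry asks whether the members of a list changed, not whether they differ from other genes, and 2229 of 2660 genes changed. The labels do not say whether the control cells were held for a further 30 min in fresh medium, so the exposure to H2O2 is not separated from the added time and the change of medium.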

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

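The library totals without rnpB, ssrA and Novel00002, the lists without mistaken matches, and the upper-quartile, abundant-RNA and limma-voom fits of the lists and all fits of the Gene Ontology terms were tests chosen after the results were seen. The 1055 genes higher and 1174 lower with H2O2 stayed within 1.5 times those counts under every alternative except the library-total scalings. Library totals gave 287 higher and 2195 lower, 177 and 1947 by at least 2-fold. Library totals without the 3 RNAs gave 502 and 1833, 323 and 1500 by at least 2-fold. Both leave out the TMM factors by construction. Without each library in turn, between 2152 and 2197 genes changed. With the replicate block 2204 genes changed, 1041 higher and 1163 lower. Deviations of same-numbered libraries had correlations of 0.068, −0.051 and 0.107, and controls 1 and 2 correlated best with other numbers, so the numbers gave no hint of pairing, and the block changed the call of 1 named gene, A1F92_05130.

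The 8 called lists became 0 with camera's estimated correlation (4 at an unadjusted p under 0.05; fry called 22), and the 49 Gene Ontology terms became 0 (54 unadjusted), against 75 terms both without a filter and on library totals without the 3 RNAs. Fry does not set a list against the other genes, so its count does not compare with those of camera. The cause of the other differences was not tested. Of 106 named genes, 0 changed the sign of their log2 fold under the other 14 alternatives. On library totals 19 did, 15 past the threshold: ileS (−0.58), pyrC (−0.35), fabI (−0.85), A1F92_05885 (−0.13), atpC (−0.021), atpD (−0.65), A1F92_05130 (−1.09), A1F92_09065 (−0.38), trxB (−1.37), tpx (−1.36), kat (−0.94), nox5 (−0.64), spx2 (−0.88), recA (−0.81), A1F92_08555 (−1.93), ctsR (−1.71), dnaK (−1.08), hrcA (−0.62) and hsp2 (−0.34), with pyrC, A1F92_05885, atpC and A1F92_09065 not past it. Without the 3 RNAs 9 did, 5 past the threshold: fabI (−0.0060), A1F92_05130 (−0.25), trxB (−0.52), tpx (−0.51), kat (−0.10), spx2 (−0.037), A1F92_08555 (−1.08), ctsR (−0.86) and dnaK (−0.23), with fabI, A1F92_05130, kat and spx2 not past it. Simulated counts with the 3 RNAs raised recovered 71.4% of genes changed 1.5-fold, but the fall of their median gene on library totals (−1.051) was short of the real one (−2.26), so recovery at the real depth was not measured.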

Other observations

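The tests of the 3 abundant RNAs, of genes of matched length, of the PTS list, of the genes from repA to the end of the map, of the predicted small RNAs and of other splits of the libraries were chosen after the results they measure had been seen, and those of gene length, of ffs and of distance from dnaA were set before. The predicted small RNAs of the authors' table went mostly opposite to rnpB, ssrA and ssrS. Of 21 tested, 14 fell, 4 rose and 3 did not pass the edgeR threshold, with a median log2 fold of −1.80 (18 lower and 1 higher on library totals). Camera gave this class an unadjusted p = 0.0067, and an unadjusted p = 0.199 with an estimated correlation.

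A run of genes at the end of the authors' map, from the replication gene repA (A1F92_15165, start 3255090) to A1F92_15265 (end 3273909), held several of the steepest rises of thiol genes. Of its 18 tested genes 14 rose, 1 fell and 3 did not pass the threshold (8 higher and 7 lower on library totals), and 7 rose by at least 32-fold, against 40 of 2642 tested genes elsewhere. These 7 were chosen after their values were seen: chpA, an mRNA interferase gene (log2 fold 5.93), the regulator A1F92_15190 (6.38), a second trxH copy, A1F92_15210 (5.64), trxA2 (5.40), dps1 (5.81), gshR4 (6.5) and A1F92_15265, a DsbA-type oxidoreductase gene (5.73).

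The median gene fell to a lower share of the libraries with H2O2. The 3 abundant RNAs do not account for that by their counts alone, since the median log2 fold was still −1.414 with rnpB, ssrA and Novel00002 left out of the totals. Annotated gene length alone does not account for it either. Protein-coding genes of 261 to 375 bases (221 genes), the lengths of Novel00002 and rnpB, had a median of −1.89 on library totals (quartiles −3.04 to −0.31). The length of the transcripts that carry these genes was not measured, so a loss by transcript length is not excluded. If stable structured RNAs as a class held their level, ffs was predicted to rise on the TMM scale, and it lay at −0.75. As a single short RNA of low count, ffs cannot decide for the class, and rnpB, ssrA and ssrS rose. A graded loss of longer transcripts stays open, with a Spearman rho of −0.086 between log2 fold and length across 2618 genes (95% bootstrap interval −0.126 to −0.048), genes not being independent replicates. A fall of messenger RNA per cell with H2O2 may also contribute and was not tested, as RNA per cell was not measured here.

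The rises of the PTS list after TMM could come from the scaling, from H2O2, or from the stage of growth. TMM scaling alone for all of them is excluded, because 18 of the 36 members that rose were also higher on library totals. These totals give shares of the counts, so a rise per cell is not shown for these 18. Of the other 18, 11 were lower on library totals and the rest did not pass the threshold there. For these other members the scaling and a rise per cell cannot be told apart without a measure of RNA per cell. Growth stage and an added 30 min in fresh medium remain untested. The labels do not say whether the control cells had them too, so these cannot be separated from H2O2.

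The run from repA to the end of the map holds replication genes, so a higher copy number of the DNA that carries it is a candidate explanation. By itself, a copy number shared by the whole run would not give log2 folds from −1.61 (A1F92_15230) to 6.5 (gshR4), and 4 of the 18 tested genes were not higher. That argues against it as the whole cause, but the rule was set after these values had been seen. Whether the run is a single piece of DNA could not be checked. A partial change stays open because DNA was not measured here. Reads shared between similar copies of trxA2, dps1, trxH and gshR4 were not tested, as no sequence was used here. A separate hypothesis, that gene dosage shifted between the replication origin and the terminus, stayed undecided: the Spearman rho of log2 fold with distance from dnaA across 2618 genes was −0.107 (95% bootstrap interval −0.145 to −0.071), short of the size of 0.2 set for it beforehand and not under 0.1.

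The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.1. The real split was the 1 split of 10 with as many changed genes (2229, highest other 0), higher genes (1055 and 0), lower genes (1174 and 0), genes higher by at least 2-fold (753 and 0), genes lower by at least 2-fold (860 and 0) and Gene Ontology terms (49 and 14). The other splits gave 0 to 3 genes with an unadjusted p under 0.05 in edgeR. Each of them mixes control and H2O2 libraries in both groups, so the H2O2 difference widens the spread within groups. Their low gene counts follow from that design and do not measure chance. For the fixed lists 3 of 10 splits called as many as the real one (8, highest other 8), and the lowest count of any split was 5. The number of lists called thus did not set the real split apart, but the other splits do not measure chance for lists or terms either. Their groups hold unequal numbers of H2O2 libraries, so part of the H2O2 difference remains between them. Camera compares a list with all other genes and can still call it from that part.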
